A study of Bos taurus with 18 samples.

How the data were processed

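Total RNA was extracted with TRIzol from biopsies of the right liver lobe of Angus heifers, and biotin-labelled cRNA made with an oligo(dT)24 primer was hybridised to an Affymetrix bovine array with 24128 probe sets. The 18 arrays came from 6 heifers of each of 3 diets (Ctrl, ISe, OSe), per the labels chosen at random among 10 assigned to each diet. Animal numbers do not repeat between diets, so no paired analysis was possible because each heifer received 1 diet. The deposited values are log2 expression per probe set, brought to a common scale by the authors. The labels name GCOS 1.2 and Partek 6.4; how probes were summarised and normalized is not given in the sources used here. The values were used as deposited, and the alternative of another pseudocount was not run because they are already logarithms.

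Array medians lay between 5.63 and 5.73 and values between 0.17 and 16.3. The background was taken as the highest mean (2.96) of 27 bacterial control probe sets without added RNA. The 112 control probe sets were left out, and the other 24016 were tested. Of these, 13292 carried 1 gene symbol (9155 genes), 86 several and 10638 none in the platform table. Gene IDs of 13263 were in the RefSeq gene table of the assembly ARS-UCD2.0 with the same symbol, and that table was used only for names.

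Comparisons were fitted with limma 3.58.1 in R 4.3.3, in 1 linear model with a mean per diet and moderated variances. The comparisons were ISe against Ctrl, OSe against Ctrl, OSe against ISe, the mean of ISe and OSe against Ctrl, and an F test over the 3 diets. P values were adjusted by Benjamini and Hochberg over all tested probe sets with a threshold of 0.05. Errors of fold changes are standard errors of the model, and the median half-width of the 95% confidence intervals was 0.20 log2 units.

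Gene lists (23) and cell marker lists (11) were written from general knowledge, and the 34 lists had at least 5 measured genes each. They were tested with camera of limma at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry, on 1 probe set per gene (the one with the highest mean). Adjustment was over the lists of a comparison. P values of members were also adjusted over the list alone, with no correction over the 34 lists and 4 comparisons. The score of a list is the mean deviation of its genes from their mean over the 18 arrays, and scores and RNA quality measures were compared by exact permutation tests. Interferon scores were compared over the diets with 100000 permutations. Spread between heifers was set against 10000 random lists matched on mean level.

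Genes named are those with 1 symbol per probe set. Per comparison they were to be the 12 higher and 12 lower with the largest change among those past the threshold, filled up to 12 genes with the smallest unadjusted p where fewer passed. All measured selenoproteins and selenium handling genes were covered, and up to 4 members per list with the largest moderated t. Comparisons of diets, their tests, the lists, this rule and the alternatives were fixed before the data were examined. The interferon score as a covariate, the tests of differences between heifers in interferon-stimulated genes and BOLA-DQB1, and the genes and relations under other observations were chosen after seeing the data.

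Alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 40% of probe sets (14409 kept), leaving out each heifer, fitting only the 2 groups compared, an intensity trend with a robust prior, array quality weights, no moderation, the mean of all probe sets of a gene, and separate sets of 3 controls. The procedure was tested on simulated data with independent genes and 50 changed probe sets per fold. These were drawn from all tested probe sets, those at background included, so recovery in expressed and variable genes may be lower. Changes of 1.25-, 1.5-, 2- and 3-fold were planted together in the same simulated data. The many true changes ease the adjusted threshold, so isolated or few changes would be recovered less often than given here. At 1.25-fold, limma recovered 40% in ISe against Ctrl, 42% in OSe against Ctrl and 38% in OSe against ISe. At 1.5-fold, limma recovered 72% in ISe against Ctrl, 64% in OSe against Ctrl and 70% in OSe against ISe, and at 2-fold 92%, 94% and 92%, with 6 false calls of 156, 9 of 158 and 5 of 153. In simulated unchanged data it called 0, whereas another split of the real heifers called as many as 922 (OSe against ISe). For lists, simulated for ISe against Ctrl alone with independent genes, 2 shifted by 0.3 log2 units were recovered by camera with either correlation and by fry, with 0 false calls. In other splits of the real heifers camera at the preset correlation called a median of 8 lists for ISe against Ctrl, 7 for OSe against Ctrl and 8 for OSe against ISe. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.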

Results

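Gene expression was measured in liver biopsies of 18 Angus heifers from a feeding trial on selenium, a trace element that animals build into selenoproteins as the amino acid selenocysteine. The heifers received 1 of 3 diets, with 6 heifers per diet on arrays out of 10 assigned to each. Control heifers (Ctrl) ate a basal diet that supplied 0.48 mg of selenium per animal and day and no added selenium. A second group (ISe) received 3 mg per animal and day as sodium selenite, an inorganic salt, and the remaining group (OSe) received the same amount as selenium-enriched yeast, an organic source. Heifers had gone 75 d without a supplement before the diets began, and the diets then ran for 80 d followed by 25 to 26 d more. Each heifer was a separate animal and is named here by its diet and animal number.

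The 18 arrays resembled each other closely, with pairwise correlations of 0.986 to 0.996 and median log2 values of 5.63 to 5.73. Of the 24016 probe sets tested, 7348 (30.6%) had a mean at or below the brightest of 27 bacterial control probe sets to which no RNA had been added (mean log2 value of 2.96), and these carry little or no signal. Messenger RNA integrity, read as the 3' minus 5' difference of control genes, was -0.29 ± 0.12 in Ctrl, -0.36 ± 0.15 in ISe and -0.31 ± 0.09 in OSe (SD, n = 6). With the oligo(dT) primer used, degraded RNA raises this difference. ISe and OSe did not differ from Ctrl in this measure beyond the spread between heifers (exact permutation p = 0.381 and p = 0.649). The first principal component held 23.9% of the variance, and 12 of its 20 leading genes were interferon-stimulated genes, which set heifers apart within every diet.

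Transcripts of the selenoproteins lay close together in the 3 diets. SELENOP, the plasma selenium carrier made by the liver, had mean log2 levels of 15.07 ± 0.04 in Ctrl, 15.06 ± 0.16 in ISe and 15.07 ± 0.08 in OSe (SD, n = 6). GPX1, the cytosolic glutathione peroxidase, was at 12.24 ± 0.15, 12.19 ± 0.17 and 12.36 ± 0.21, and DIO1, the deiodinase that activates thyroid hormone, was at 13.01 ± 0.29, 12.79 ± 0.47 and 12.88 ± 0.45. SEPHS2, which makes the selenium donor for selenocysteine, differed from Ctrl by -0.24 ± 0.12 with ISe and -0.29 ± 0.12 with OSe (log2 fold change ± SE), and all 6 OSe heifers lay below the Ctrl mean. SELENOS, a membrane protein of the endoplasmic reticulum, differed from Ctrl by 0.39 ± 0.16 with ISe (5 of 6 heifers above the Ctrl mean) and 0.31 ± 0.16 with OSe (6 of 6).

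None of these differences passed limma's test. The array measured 17 of the 24 listed selenoproteins, and the smallest adjusted p, adjusted over the list alone, was 0.468 for ISe against Ctrl, 0.391 for OSe against Ctrl and 0.736 for OSe against ISe. Over all probe sets the adjusted p of SELENOS was 1 for ISe against Ctrl, and that of SEPHS2 was 1.00 for OSe against Ctrl. The 95% confidence interval stayed within 0.5 log2 units of no change (1.41-fold) for 12 of the 16 selenoproteins above the bacterial controls in ISe against Ctrl, 11 in OSe against Ctrl and 14 in OSe against ISe. GPX3, the plasma glutathione peroxidase, differed by -0.82 ± 0.46 in OSe against Ctrl, but its mean of 3.90 in Ctrl was near the bacterial controls and heifer Ctrl 16 alone was at 6.19. SELENOM was below the bacterial controls and differed by 0.27 ± 0.13 in OSe against Ctrl. Other members such as GPX4 (-0.06 ± 0.11 with ISe and 0.03 ± 0.11 with OSe), TXNRD1 (0.09 ± 0.14 and 0.12 ± 0.14) and TXNRD2 (-0.16 ± 0.20 and -0.19 ± 0.20) varied within their errors. As a group, the selenoproteins had a median log2 fold change of -0.02 in ISe against Ctrl, 0.06 in OSe against Ctrl and 0.01 in OSe against ISe (adjusted p = 0.893, 0.685 and 0.511 with camera of limma); in OSe against Ctrl the mean was -0.02 and in OSe against ISe -0.01, opposite in sign to the median.

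**Figure D1:**
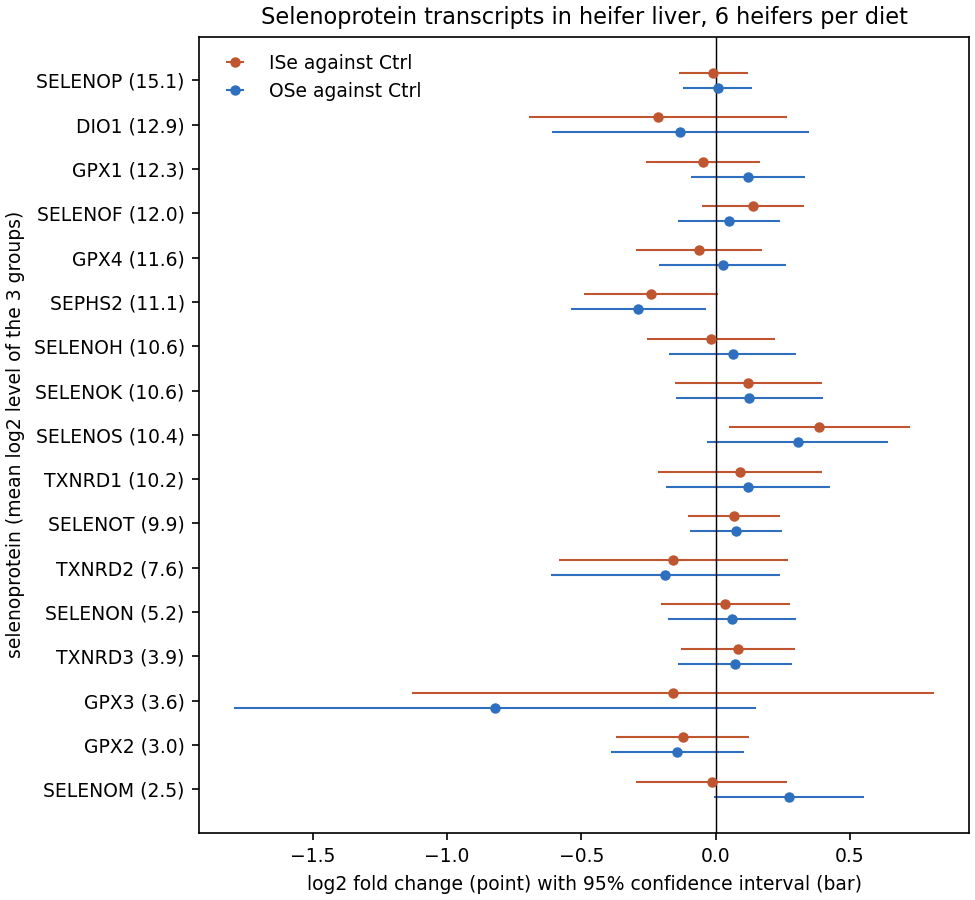
Log2 fold change (point) and 95% confidence interval (bar) of the 17 measured selenoproteins against Ctrl, 6 heifers per diet, ordered by mean log2 level (in parentheses). Intervals of most transcripts cross 0, among them SELENOP at -0.01 with ISe and 0.01 with OSe.

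Genes for selenium handling and selenocysteine synthesis gave the same picture. Of 13 listed genes 8 were measured, and the log2 fold changes ran from -0.14 (SCLY, which releases selenium from selenocysteine) to 0.20 (SARS1, the seryl-tRNA synthetase) in ISe against Ctrl. In OSe against Ctrl they ran from -0.15 (SCLY) to 0.31 ± 0.18 (SARS1, above the Ctrl mean in 6 of 6 heifers). The smallest adjusted p, adjusted over the list alone, was 0.888 in ISe against Ctrl, 0.849 in OSe against Ctrl and 0.989 in OSe against ISe.

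The comparison of ISe with Ctrl asked what an inorganic supplement does to liver expression. The lowest unadjusted p belonged to STK3, a kinase of the Hippo pathway, at 5.97 ± 0.11 in Ctrl and 6.35 ± 0.15 in ISe (SD, n = 6), a log2 fold change of 0.38 ± 0.07 (SE). LGI4, a secreted protein known from myelination, differed by -0.46 ± 0.09. The circadian repressor BHLHE40 differed by -1.42 ± 0.35, RUBCNL, a regulator of autophagy, by -1.01 ± 0.26, and P3H2, a collagen prolyl hydroxylase, by 0.61 ± 0.15. In each of these 5 genes all 6 ISe heifers lay on the same side of the Ctrl mean. Genes named here were chosen by p or t in the same data, so such counts of heifers add nothing to those tests. PCK1, which encodes a rate-limiting enzyme of gluconeogenesis, differed by -0.64 ± 0.18 (6 of 6 heifers below the Ctrl mean).

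No probe set reached an adjusted p of 0.05 with limma in ISe against Ctrl. The count was 0 also without moderation of the variances, with array weights and with a robust intensity trend, and the adjusted p was 1 for each gene named here. At an unadjusted p under 0.05 there were 801 probe sets, where chance gives 1200.8, and at a p under 0.01 there were 130 (73 higher and 57 lower, chance 240.16). The latter count was 84 without heifer ISe 22 and 339 without heifer ISe 7. Its median over other splits of the heifers was 142. The other genes with the smallest unadjusted p were GET1 (0.36 ± 0.08), DHRS4, a carbonyl reductase (-0.42 ± 0.10), AZIN1 (-0.26 ± 0.07), ACTR8 (0.49 ± 0.12), C29H11orf98 (0.36 ± 0.09), the plasma glycoprotein A1BG (-0.47 ± 0.12) and KNG1, the kininogen precursor (-0.18 ± 0.04). A brighter KNG1 probe set gave -0.11 ± 0.06. Half-widths of the 95% confidence intervals had a median of 0.20 log2 units (1.15-fold) over all probe sets with 6 arrays per diet. Those near background are included, and many genes had wider intervals.

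Among gene groups in ISe against Ctrl, proteasome genes were higher in 30 of 32 (median log2 fold change 0.14), among them PSMD4 (0.23 ± 0.07), PSMD2 (0.24 ± 0.08), PSMD10 (0.26 ± 0.10) and PSMD14 (0.34 ± 0.13). All 22 heat shock chaperones were higher (median 0.23), among them HSP90AB1 (0.22 ± 0.08), CCT2 (0.30 ± 0.12) and HSPA4 (0.32 ± 0.14). Proteasome scores were highest in ISe 26 (0.30) and ISe 22 (0.24), while the other 4 ISe heifers (-0.10 to 0.08) lay within the range of Ctrl (-0.26 to 0.09). Heat shock scores were highest in ISe 22 (0.55) and ISe 29 (0.47), with -0.19 to 0.14 in the other 4 and -0.26 to -0.01 in Ctrl. Lymphocyte markers were lower in 13 of 17 (median -0.32), with the immunoglobulin genes IGHM (-1.16 ± 0.40) and JCHAIN (-0.92 ± 0.35), the cytotoxic granule gene GNLY (-1.21 ± 0.47) and the T cell gene CD3G (-0.39 ± 0.17) below the Ctrl mean in all 6 heifers. The haemoglobin gene HBB, the 1 erythroid marker of 8 above the bacterial controls, was likewise at -1.17 ± 0.48 (6 of 6 heifers below), and how much blood each biopsy held was not measured here. Cell cycle genes were lower in 27 of 32 (median -0.23), of which 21 lay above the bacterial controls. Their scores were high in 2 controls, Ctrl 17 (0.65) and Ctrl 21 (0.59), while the other 4 controls (-0.20 to -0.10) overlapped the 6 ISe heifers (-0.24 to -0.14). TYMS was at -0.79 ± 0.31, AURKB at -0.23 ± 0.11 and CENPF at -0.49 ± 0.27, and CDC20 (-0.21 ± 0.10) was below the bacterial controls.

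At the preset correlation between genes of 0.01, camera called 11 of the 34 lists in this comparison, 4 higher and 7 lower. The adjusted p was 3.97e-09 for the proteasome (adjusted p = 0.741 with an estimated correlation) and 3.18e-07 for heat shock chaperones (adjusted p = 0.741 with an estimated correlation). It was 7.04e-07 for lymphocyte markers (adjusted p = 0.128 with an estimated correlation) and 3.14e-06 for cell cycle genes (adjusted p = 0.746 with an estimated correlation). These 4 calls held when any 1 of the 18 heifers was left out, with highest adjusted p of 1.13e-05, 9.76e-05, 3.09e-04 and 0.00556 in that order, although this leaves in place 1 of the 2 high controls for the cell cycle and the lymphocyte markers, and 1 of the 2 high ISe heifers for the proteasome and heat shock chaperones. Lymphocyte scores were 0.53 in Ctrl 21 and 0.35 in Ctrl 17, and -0.13 to 0.12 in the other 4 controls, beside -0.43 to -0.00 in ISe. In exact permutation tests of the scores, p was 0.104 for the proteasome, 0.0823 for heat shock chaperones and 0.145 for the cell cycle (adjusted p = 0.789 for each). With the estimated correlation camera called 0 lists, and fry called 0 (smallest adjusted p 0.441, and 0.315 for change in either direction). No member of a list passed limma's test over all probe sets or adjusted over the list alone.

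The other 7 calls in ISe against Ctrl ended when single heifers were left out. Immediate early and injury response genes, which react within minutes to tissue handling, were lower in 18 of 23 (median -0.20, adjusted p = 4.14e-04, and adjusted p = 0.746 with an estimated correlation), with GADD45A at -0.71 ± 0.28 and JUNB at -0.50 ± 0.24. Their adjusted p was 0.0732 without heifer Ctrl 1 and 0.120 without Ctrl 17. All 29 interferon-stimulated genes were higher (median 0.71, adjusted p = 4.14e-04, and adjusted p = 0.872 with an estimated correlation), but single genes had wide errors, such as OAS1X at 2.15 ± 1.51, and the adjusted p was 0.286 without heifer ISe 22. Cytosolic ribosomal proteins were lower in 58 of 66 by a median of -0.06 (adjusted p = 1.09e-04, and adjusted p = 0.872 with an estimated correlation), with RPL38 at -0.13 ± 0.09, and the adjusted p was 0.145 without heifer ISe 26. Fatty acid oxidation genes were lower in 21 of 31 (median -0.04, adjusted p = 0.00904, and adjusted p = 0.746 with an estimated correlation), with ACADM at -0.13 ± 0.05 and ACOT8 at -0.61 ± 0.26. Their adjusted p was 0.0532 without ISe 22, 0.0591 without Ctrl 10, 0.0703 without Ctrl 21 and 0.213 without ISe 26.

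Genes of the unfolded protein response were higher in 18 of 23 (median 0.10, adjusted p = 0.0442, and adjusted p = 0.872 with an estimated correlation), among them the chaperone HYOU1 at 0.66 ± 0.32 and DDIT3 at 0.71 ± 0.40. This call ended without any 1 of Ctrl 1, Ctrl 16, Ctrl 21, ISe 22, ISe 26, ISe 29, OSe 8, OSe 14, OSe 23 and OSe 25 (adjusted p from 0.0512 to 0.608). Genes of cholesterol biosynthesis were lower in 13 of 17 (median -0.05, adjusted p = 0.0442, and adjusted p = 0.872 with an estimated correlation), with INSIG1 at -0.34 ± 0.23 and MVD at -0.20 ± 0.13. Leaving out any 1 of Ctrl 1, Ctrl 10, Ctrl 17, Ctrl 21, ISe 11, ISe 22, ISe 26, OSe 8, OSe 14, OSe 23 and OSe 25 ended this call (adjusted p from 0.0512 to 0.827). Complement and coagulation genes were lower in 16 of 30 (median -0.02, adjusted p = 0.0442, and adjusted p = 0.833 with an estimated correlation), with C8A at -0.17 ± 0.09. This call ended without any 1 of Ctrl 16, Ctrl 17, ISe 7, ISe 18, ISe 29, OSe 14, OSe 23 and OSe 25 (adjusted p from 0.0512 to 0.526). The count of lists called was 7 without ISe 22 and 7 without ISe 26.

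The comparison of OSe with Ctrl asked the same of the organic supplement. PRKCI, an atypical protein kinase C, was at 7.78 ± 0.35 in Ctrl and 6.99 ± 0.42 in OSe (SD, n = 6), a log2 fold change of -0.79 ± 0.19 (SE). The related transcription factors KLF10 and KLF11 differed by -0.76 ± 0.18 and -0.64 ± 0.16, WDR46, a nucleolar protein, by 0.50 ± 0.12, and P3H2 by 0.56 ± 0.15. In each of these 5 genes all 6 OSe heifers lay on the same side of the Ctrl mean, again after selection by p. P3H2 was also named in ISe against Ctrl, which uses the same Ctrl arrays. PPARA, the nuclear receptor that controls fatty acid oxidation, differed by 0.63 ± 0.23 (6 of 6 heifers above the Ctrl mean), and the immediate early gene FOS by -1.69 ± 0.96. FOS was at 11.7 in Ctrl 17, and near that level in Ctrl 1, and its range in the other 4 controls (5.69 to 9.44) spanned that of the 6 OSe heifers (5.63 to 8.26) but for the lowest of these.

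In OSe against Ctrl, too, limma called 0 probe sets, as did the fits without moderation, with array weights and with a robust intensity trend, and the smallest adjusted p was 1.00. There were 764 probe sets at an unadjusted p under 0.05 (chance 1200.8) and 142 at a p under 0.01 (80 higher and 62 lower, chance 240.16). The latter count was 89 without heifer Ctrl 1 and 93 without heifer OSe 25. Its median over other splits of the heifers was 132. The remaining genes with the smallest unadjusted p were PTPN23 (0.21 ± 0.05), HAGHL (0.37 ± 0.10), WRAP53 (0.22 ± 0.06, 5 of 6 heifers above the Ctrl mean), ZCCHC8 (0.22 ± 0.06), B3GNT2 (-0.27 ± 0.08), VPS28, a part of the endosomal sorting machinery (0.17 ± 0.05), and SYNPO (0.24 ± 0.07), which was below the bacterial controls.

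Among gene groups in OSe against Ctrl, immediate early and injury response genes were lower in 22 of 23 (median log2 fold change -0.37), with GADD45A at -0.79 ± 0.28, NR4A1 at -0.72 ± 0.39 and DUSP1 at -1.20 ± 0.67. Genes of the unfolded protein response were higher in 20 of 23 (median 0.17), among them P4HB (0.17 ± 0.07), HYOU1 (0.77 ± 0.32), MANF (0.85 ± 0.40) and CRELD2 (0.76 ± 0.40), each above the Ctrl mean in all 6 heifers. Camera called both at the preset correlation (adjusted p = 2.22e-05 for each), and the adjusted p was 0.601 for each with an estimated correlation. Both calls held when any 1 heifer was left out (highest adjusted p 0.00945 and 0.00232). The immediate early score was high in 2 controls, Ctrl 1 (1.08) and Ctrl 17 (1.13), and the other 4 (-0.48 to 0.26) lay within the range of the OSe heifers (-0.65 to 0.25) or next to it. Between the diets it differed by -0.46 (exact permutation p = 0.197, adjusted p = 0.742).

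Camera called 9 lists in OSe against Ctrl at the preset correlation, 7 higher and 2 lower, 0 with an estimated correlation, and fry called 0 (smallest adjusted p 0.579, and 0.890 for change in either direction). No member of a list passed limma's test over all probe sets or adjusted over the list alone. Plasma proteins and markers of non-parenchymal cells were among the 9. Complement and coagulation genes were higher in 25 of 30 (median 0.06, adjusted p = 0.00582, and adjusted p = 0.601 with an estimated correlation), with the protein C gene PROC at 0.17 ± 0.08. Acute phase proteins were higher in 15 of 18 (median 0.13, adjusted p = 0.0102, and adjusted p = 0.601 with an estimated correlation), with ITIH1 at 0.13 ± 0.05 and the fibrinogen gene FGB at 0.44 ± 0.25. Without heifer OSe 25 the adjusted p was 0.0547 for complement and coagulation and 0.0913 for acute phase proteins. Kupffer cell and macrophage markers were higher in 13 of 14 (median 0.24, adjusted p = 0.00788, and adjusted p = 0.831 with an estimated correlation), with AIF1 at 0.41 ± 0.25 and C1QC at 0.28 ± 0.18. Their adjusted p was 0.0622 without Ctrl 1 and 0.956 without OSe 25. Stellate cell and fibroblast markers were higher in 13 of 16 (median 0.17, adjusted p = 0.0102, and adjusted p = 0.601 with an estimated correlation), with SPARC at 0.29 ± 0.11, and the adjusted p was 0.0592 without OSe 8. The count of lists was 4 without OSe 25 and 14 without OSe 23.

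Genes of oxidative phosphorylation were higher in 52 of 73 in OSe against Ctrl (median 0.05, adjusted p = 0.0206, and adjusted p = 0.839 with an estimated correlation), with UQCR11 at 0.18 ± 0.09. Leaving out any 1 of Ctrl 10, Ctrl 16, Ctrl 17, OSe 12 and OSe 19 ended this call (adjusted p from 0.0786 to 0.468). Fatty acid oxidation genes were lower in 23 of 31 (median -0.05, adjusted p = 0.0295, and adjusted p = 0.601 with an estimated correlation). Estimates of its members had both signs, with PPARA at 0.63 ± 0.23 and ANGPTL4, an inhibitor of lipoprotein lipase, at -0.54 ± 0.21, and the call ended without any 1 of Ctrl 10, Ctrl 21, OSe 8 and OSe 25 (adjusted p from 0.0977 to 0.168). All 29 interferon-stimulated genes were higher (median 0.42, adjusted p = 0.0363, and adjusted p = 0.839 with an estimated correlation), with STAT2 at 0.29 ± 0.24. It ended without any 1 of Ctrl 1, Ctrl 6, Ctrl 10, Ctrl 16, OSe 8 and OSe 25 (adjusted p from 0.118 to 0.968).

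The comparison of OSe with ISe addressed the chemical form at an equal dose of selenium. STK3 was at 6.35 ± 0.15 in ISe and 6.02 ± 0.12 in OSe (SD, n = 6), a log2 fold change of -0.33 ± 0.07 (SE), and LGI4 differed by 0.37 ± 0.09. Both genes were also named in ISe against Ctrl, which uses the same ISe arrays, so their return is not independent evidence. The same holds for gene lists called in several comparisons, which share the arrays of a diet. GCLM, the modifier subunit of the enzyme that limits glutathione synthesis, differed by -0.27 ± 0.07 (5 of 6 OSe heifers below the ISe mean). HGFAC, the activator of hepatocyte growth factor, differed by 0.23 ± 0.05, TLN1, a linker of integrins to actin, by 0.33 ± 0.08 and the collagen hydroxylase P4HA2 by -0.62 ± 0.17. A probe set of the growth factor IGF2 differed by 0.36 ± 0.09, and a brighter IGF2 probe set by 0.24 ± 0.14.

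In OSe against ISe limma called 0 probe sets, as did the fits without moderation, with array weights and with a robust intensity trend, and the smallest adjusted p was 0.999. GCLM alone passed when the p was adjusted over the list alone, here the NRF2 targets (0.0206), while its adjusted p over all probe sets was 0.999. Each of the 34 lists was adjusted in this way, so a member can pass by chance. At an unadjusted p under 0.05 there were 712 probe sets (chance 1200.8), and at a p under 0.01 there were 99 (53 higher and 46 lower, chance 240.16). The latter count was 172 without ISe 7, 154 without ISe 18, 65 without OSe 23 and 228 with array weights. Its median over other splits of the heifers was 142. The other genes with the smallest unadjusted p were NCK2 (0.22 ± 0.05), EVA1B (0.38 ± 0.10), ENC1 (-0.89 ± 0.25), ATL2 (-0.30 ± 0.08) and CCPG1 (-0.26 ± 0.07). The 95% intervals had a median half-width of 0.20 log2 units over all probe sets, those near background included. For selenoproteins the median was 0.25 and the widest 0.97. Differences below 0.20 between the sources of selenium, and for many genes larger ones, are left open.

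Among gene groups in OSe against ISe, complement and coagulation genes were higher with the organic source in 29 of 30 (median log2 fold change 0.07), with PROC at 0.24 ± 0.08, C8A at 0.25 ± 0.09 and C6 at 0.13 ± 0.06. Proteasome genes were lower in 30 of 32 (median -0.11), with PSMA4 at -0.38 ± 0.13 and PSMB5 at -0.23 ± 0.09, and heat shock chaperones in 20 of 22 (median -0.15), with HSPD1 at -0.11 ± 0.04 and CRYAB at -0.94 ± 0.42. Lymphocyte markers were higher in 14 of 17 (median 0.23), with PTPRC at 0.22 ± 0.10 and IGHM at 0.83 ± 0.40. HBB was at 0.94 ± 0.48 (6 of 6 heifers above the ISe mean), and here too the blood in each biopsy was not measured. Camera gave adjusted p of 7.53e-08 for complement and coagulation, 5.19e-07 for the proteasome, 3.10e-04 for heat shock chaperones and 4.68e-04 for lymphocyte markers at the preset correlation. With an estimated correlation the adjusted p was 0.251, 0.736, 0.772 and 0.251 in that order. These 4 calls held when any 1 heifer was left out (highest adjusted p 2.59e-05, 0.00191, 0.0394 and 0.0120). For the proteasome and heat shock chaperones this again leaves 1 of 2 high ISe heifers in place (ISe 22 and ISe 26, ISe 22 and ISe 29), and the other 4 ISe heifers overlapped OSe in both scores (-0.16 to 0.07 and -0.32 to 0.31 in OSe).

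Camera called 12 lists in OSe against ISe, 10 higher and 2 lower, 0 with an estimated correlation, and fry called 0 (smallest adjusted p 0.503, and 0.947 for change in either direction). Cell cycle genes were higher in 25 of 32 (median 0.24, adjusted p = 5.30e-04, and adjusted p = 0.772 with an estimated correlation), with MCM6 at 0.62 ± 0.30, and the adjusted p was 0.745 without OSe 8, whose cell cycle score of 1.18 stood apart. Kupffer cell and macrophage markers were higher in 12 of 14 (median 0.22, adjusted p = 9.55e-04, and adjusted p = 0.772 with an estimated correlation), with CSF1R at 0.37 ± 0.23, and the adjusted p was 0.112 without ISe 18 and 0.570 without OSe 25. Acute phase proteins were higher in 15 of 18 (median 0.10, adjusted p = 0.0129, and adjusted p = 0.736 with an estimated correlation), with ITIH4 at 0.30 ± 0.17, and the adjusted p was 0.0790 without ISe 7, 0.140 without OSe 25 and 0.251 without ISe 18. Genes of gluconeogenesis and glycolysis were higher in 24 of 30 (median 0.05, adjusted p = 0.0152, and adjusted p = 0.251 with an estimated correlation), with GAPDH at 0.14 ± 0.06 and ME2 at 0.49 ± 0.22. This call ended without any 1 of ISe 18, ISe 26, OSe 12, OSe 14 and OSe 19 (adjusted p of 0.0590 or more). The count of lists was 6 without ISe 18 and 7 without OSe 19.

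Of the remaining lists called in OSe against ISe, stellate cell and fibroblast markers were higher in 12 of 16 (median 0.11, adjusted p = 0.0254, and adjusted p = 0.772 with an estimated correlation), with SPARC at 0.26 ± 0.11. This call ended without any 1 of ISe 11, ISe 18, ISe 22, ISe 26, OSe 8 and OSe 19 (adjusted p of 0.0536 or more). Endothelial markers were higher in 9 of 15 (median 0.12, adjusted p = 0.0475, and adjusted p = 0.772 with an estimated correlation), with EGFL7 at 0.27 ± 0.11. This call ended without any 1 of Ctrl 6, Ctrl 10, Ctrl 21, ISe 18, ISe 22, ISe 26, OSe 12, OSe 14 and OSe 19 (adjusted p from 0.0515 to 0.450). Genes of oxidative phosphorylation were higher in 48 of 73 (median 0.02, adjusted p = 0.0416, and adjusted p = 0.804 with an estimated correlation), with ATP5ME at 0.19 ± 0.07. It ended without any 1 of ISe 7, ISe 18, ISe 22, OSe 12 and OSe 19 (adjusted p from 0.196 to 0.687). Genes of the unfolded protein response were higher in 17 of 23 (median 0.11, adjusted p = 0.0416, and adjusted p = 0.804 with an estimated correlation), with P4HB at 0.14 ± 0.07. With camera it ended without any 1 of ISe 11, ISe 18, OSe 14, OSe 19 and OSe 25, and without ISe 7 its direction turned to lower (limma's camera, adjusted p = 0.641).

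**Figure D2:**
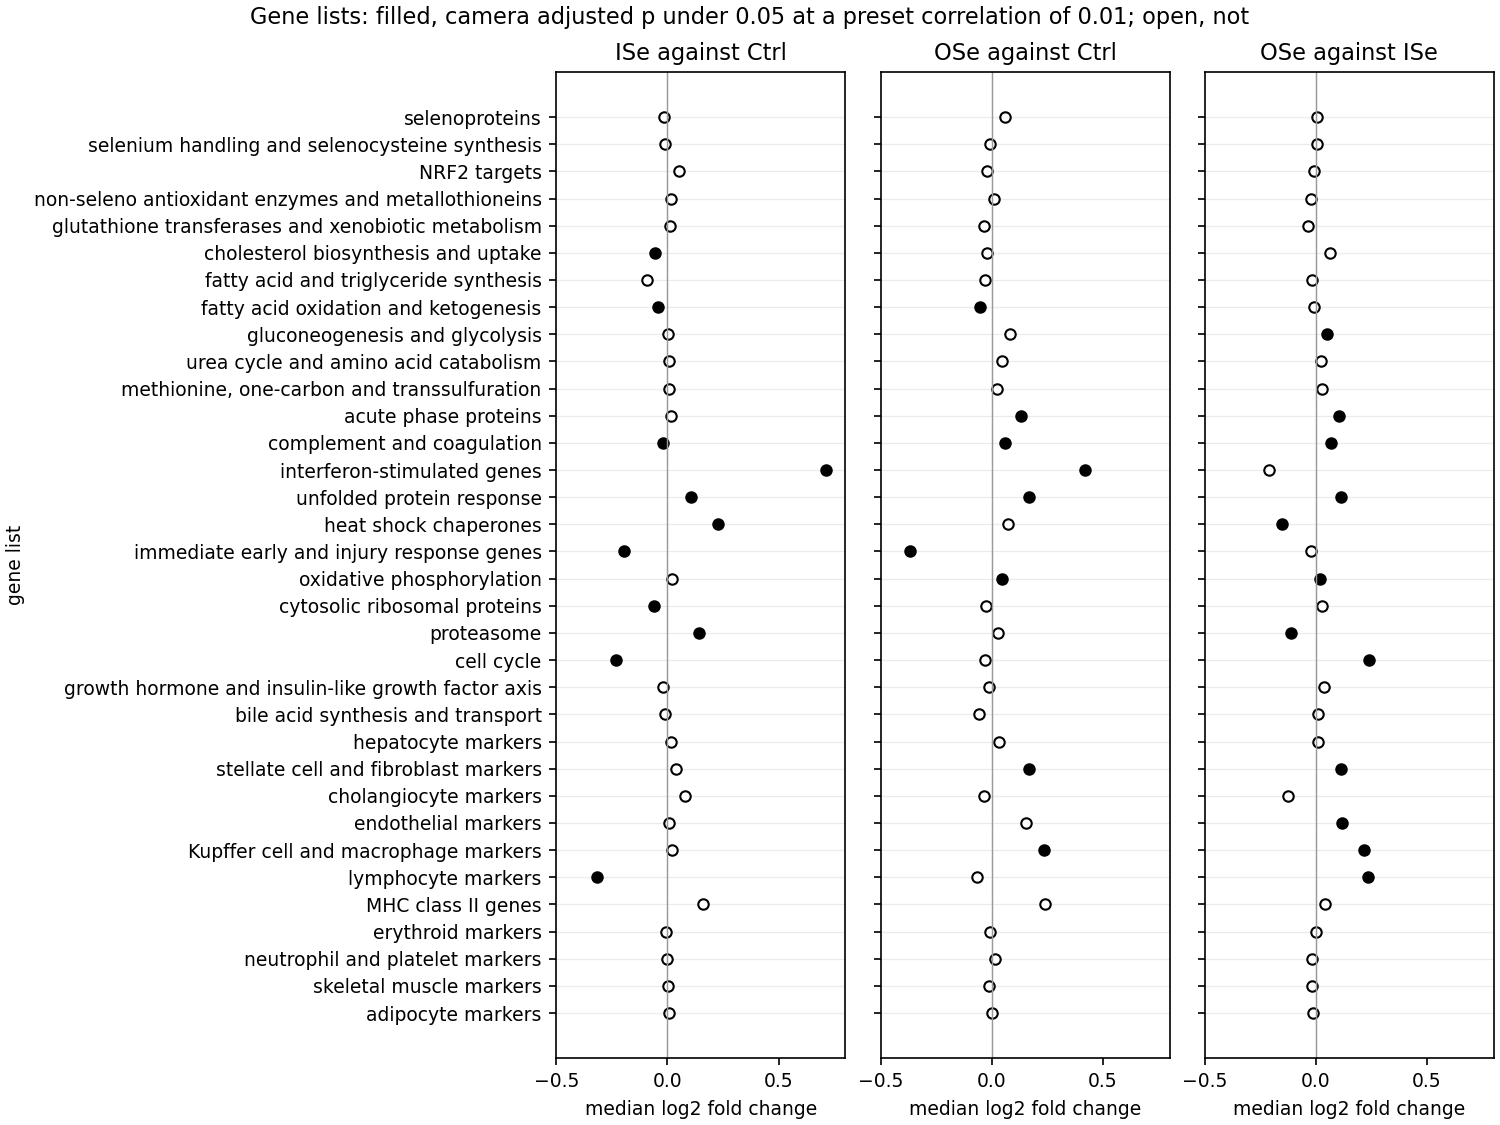
Median log2 fold change of each of the 34 gene lists in the 3 comparisons, with filled circles for lists called by camera at the preset correlation of 0.01 and open circles for the others. The filled circles number 11, 9 and 12 from left to right, and with an estimated correlation none of them stays below an adjusted p of 0.05.

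The remaining 17 lists were called in none of the 3 comparisons, with adjusted p of 0.0722 to 0.977. In the order ISe against Ctrl, OSe against Ctrl and OSe against ISe, the adjusted p was 0.977, 0.796 and 0.733 for selenium handling, 0.972, 0.544 and 0.511 for NRF2 targets, and 0.893, 0.913 and 0.696 for other antioxidant enzymes and metallothioneins. It was 0.877, 0.123 and 0.359 for glutathione transferases and xenobiotic metabolism, and 0.0722, 0.309 and 0.506 for fatty acid and triglyceride synthesis, where the lipogenic regulator MLXIPL was at -0.35 ± 0.15 in ISe against Ctrl. The urea cycle and amino acid catabolism gave 0.893, 0.357 and 0.319, and methionine and one-carbon metabolism 0.742, 0.744 and 0.339, with the methyltransferase BHMT at 0.70 ± 0.33 in OSe against ISe. The growth hormone and insulin-like growth factor axis gave 0.346, 0.846 and 0.374, and bile acid synthesis and transport 0.118, 0.309 and 0.581, with CYP7A1 at -0.70 ± 0.45 in OSe against Ctrl. Among cell markers, hepatocytes gave 0.877, 0.188 and 0.374, cholangiocytes 0.742, 0.846 and 0.403, and MHC class II genes 0.226, 0.0971 and 0.696. Erythroid markers gave 0.291, 0.599 and 0.511, with HBB, a haemoglobin chain, at -1.17 ± 0.48 in ISe against Ctrl, and neutrophil and platelet markers 0.893, 0.846 and 0.755. Skeletal muscle gave 0.893, 0.251 and 0.374, and adipocytes 0.893, 0.644 and 0.696. Median, mean and test had the same sign in the 32 called results, and differed in sign in 23 of the 70 without a call.

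Mean scores of the 34 lists were also compared heifer by heifer with exact permutation tests, in which 6 heifers against 6 allow 924 assignments. The hepatocyte marker score was 0.03 ± 0.02 in OSe and -0.03 ± 0.04 in Ctrl (SD, n = 6; exact permutation p = 0.0108, adjusted p = 0.221 over the lists). The lymphocyte score differed by -0.36 between ISe and Ctrl (exact permutation p = 0.0173, adjusted p = 0.589) and by 0.26 between OSe and ISe (exact permutation p = 0.0216, adjusted p = 0.589). Scores of the unfolded protein response and of stellate cell markers differed between OSe and Ctrl by 0.25 and 0.18 (exact permutation p = 0.0195 for each, adjusted p = 0.221). In all, 7 scores had an exact p under 0.05 and 0 an adjusted p under 0.05.

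Supplemented heifers as a whole were compared with Ctrl by the mean of ISe and OSe. IGFBP3, the main carrier of insulin-like growth factors in plasma, differed by 0.41 ± 0.11 and alone passed limma's test when adjusted over the list alone (0.0302). Its adjusted p over all probe sets was 0.999, and it was above the Ctrl mean in 6 of 6 ISe and 6 of 6 OSe heifers. Adjustment over a list alone was made for 34 lists in 4 comparisons, so some members can pass by chance. The counts of heifers follow that selection and add nothing to it. With limma 0 probe sets passed, 802 had an unadjusted p under 0.05 (chance 1200.8), and 0 passed without moderation or with array weights. Camera called 9 lists, 4 higher and 5 lower, and 0 with an estimated correlation (smallest adjusted p 0.696). An F test over the 3 diets with limma likewise called 0 probe sets, with 683 at an unadjusted p under 0.05.

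Fold changes of ISe and OSe against Ctrl correlated across 9155 genes (Pearson r 0.541, Spearman rho 0.505), and 69.1% had the same sign. Both comparisons use the same 6 Ctrl arrays, and unchanged groups simulated against shared controls gave a mean r of 0.501 and 66.7% with the same sign. The covariance was 0.0175 beside a simulated 0.0183. With a separate set of 3 controls for each comparison, the mean r over 20 splits was 0.034 (from -0.116 to 0.167). Genes are not independent replicates, so no p is given.

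Interferon-stimulated genes differed widely between heifers within each diet. The mean score of the 29 measured genes was above 0 in 7 heifers, namely Ctrl 17 (1.57), Ctrl 21 (0.58), ISe 11 (0.99), ISe 22 (2.28), ISe 26, OSe 8 (1.70) and OSe 25 (1.93), and from -1.27 to -0.32 in the other 11. ISG15, a ubiquitin-like protein induced by type I interferon, ran from 7.58 (Ctrl 10) to 14.5 (ISe 22), and the antiviral GTPase MX2 from 2.83 (Ctrl 1) to 10.7 (ISe 22). Diet accounted for 5.65% of the sum of squares of the score (permutation p = 0.636, 100000 permutations). The score ranged over 2.85 to 3.39 within diets, and the largest difference between diet means was 0.73. The upper 95% bound of that difference was 2.39, so a large difference between diets is not excluded. With the score as a covariate, an alternative chosen after seeing the data, 6 lists were called in ISe against Ctrl in place of 11. The interferon list, 1 of the 11, was not tested in that fit.

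**Figure D3:**
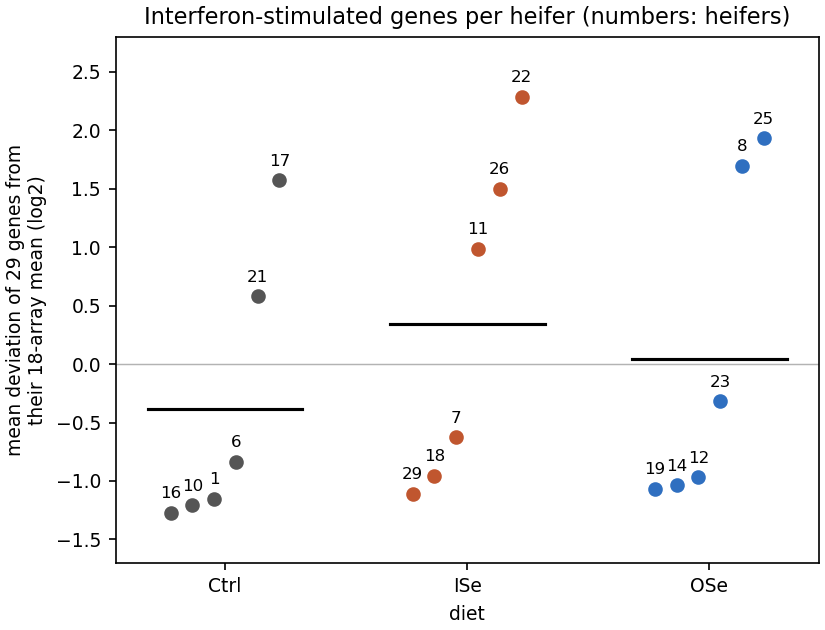
Mean deviation of 29 interferon-stimulated genes from their mean over all 18 arrays (log2, vertical axis) for each heifer (point, with animal number) by diet, with the diet mean as a bar. Each diet holds heifers above 0 (2 in Ctrl, 3 in ISe, 2 in OSe) and below it, with the highest at 2.28 (ISe 22).

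MHC class II genes also differed between heifers of a diet, by probe set. BOLA-DRA ranged only from 12.1 to 13.1 over the 18 heifers, while a BOLA-DQB1 probe set ranged from 2.62 to 11.3 and another from 2.48 to 10.4. At a log2 level of 8, the first was above it in 10 heifers, the second in 6, both in 1 and neither in 3. BOLA-DQA5 was between 10.1 and 10.5 in OSe 12, ISe 22 and ISe 26 and between 2.09 and 2.32 in the other 15 heifers, which gave its wide error in ISe against Ctrl (2.78 ± 1.71).

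**Figure D4:**
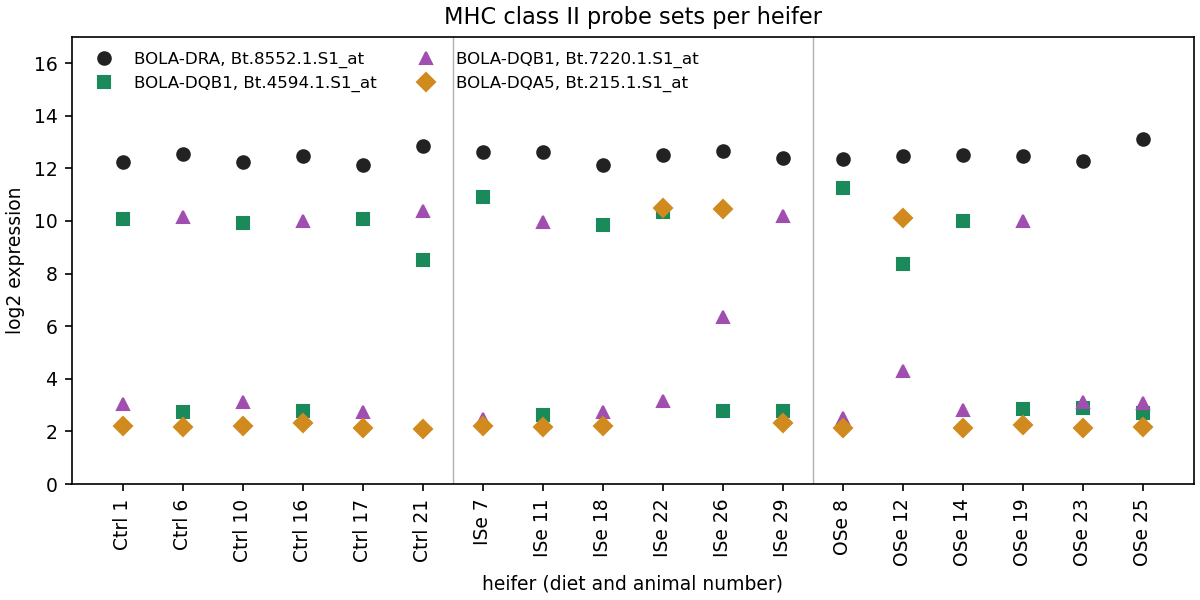
Log2 expression (vertical axis) of 4 MHC class II probe sets in each of the 18 heifers (horizontal axis, grouped by diet). BOLA-DRA stays between 12.1 and 13.1, the 2 BOLA-DQB1 probe sets shown are both above 8 in 1 heifer and neither in 3, and BOLA-DQA5 is high in 3.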

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

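The tests of the interferon-stimulated genes and of the BOLA-DQB1 probe sets were chosen after the result was seen; the counts over other splits of the heifers were planned. Among 276 groups of 6 values, 24 held a heifer far from the other 5, where chance flags about 1 in 20 (13.8). OSe 25 accounts for 6 of them, and Ctrl 16 and OSe 8 for 4 each.

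Several selenium genes had such a heifer. GPX3 was at 6.19 in Ctrl 16 (others 3.06 to 4.16) and GPX2 at 3.75 in Ctrl 16 (2.88 to 3.00). TXNRD3 was at 4.25 in ISe 7 (3.79 to 3.85) and at 4.38 in OSe 23 (3.70 to 3.84). SELENON was at 4.66 in Ctrl 17 (5.16 to 5.32), SEPHS1 at 7.68 in Ctrl 17 (7.82 to 7.90) and TXNRD1 at 9.43 in Ctrl 1 (10.14 to 10.37). GPX4 was at 11.35 in OSe 8 (11.69 to 11.79). In OSe 25, SELENOT was at 10.22 (9.78 to 9.94), SEPHS2 at 10.76 (10.98 to 11.09) and TRNAU1AP at 6.87 (6.22 to 6.33).

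Other named genes with a distant heifer were GET1 at 10.07 in OSe 8 (9.63 to 9.76), B3GNT2 at 11.32 in OSe 8 (10.94 to 11.07), PTPN23 at 7.30 in ISe 26 (7.05 to 7.13), and KLF11 at 11.28 in Ctrl 1 (10.43 to 10.75) and 9.47 in OSe 25 (10.06 to 10.30). Scores of lists did so for the cell cycle in OSe 8 (1.18), Kupffer cell markers in OSe 25 (1.18), neutrophil and platelet markers in OSe 25 (0.65), endothelial markers in OSe 14 (0.45) and hepatocyte markers in ISe 7 (-0.065). In Ctrl 16 the scores of cholesterol biosynthesis (-0.36) and of fatty acid and triglyceride synthesis (-0.33) were low, and in ISe 26 that of the urea cycle (-0.32).

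Splits of the heifers, 100 for each result with the real diets as 1 of them, were compared. The counts of splits given here include the real diets. At an adjusted p under 0.05 the real count is 0, which all 100 splits reach whatever the data, so this says nothing about chance; the highest other was 2 for ISe against Ctrl, 3 for OSe against Ctrl, 922 for OSe against ISe, 0 for the mean of both and 2 over the 3 diets (limma; 801, 764, 712, 802 and 683 at unadjusted p under 0.05). At unadjusted p under 0.01, 54, 39 and 80 splits gave as many as the real 130, 142 and 99 (highest other 2396, 848 and 2566), so chance cannot be excluded for them. Counts that high point to a structure of the samples whose source was not tested, and hybridisation or scan batches are not given in the sources used here. As many lists were called in 22, 31 and 14 splits (real 11, 9 and 12; highest other 17, 14 and 15). A correlation as high as 0.541 came from 42 splits (highest other 0.833). Chance cannot be excluded for the lists or the correlation either.

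Interferon-stimulated genes differed between heifers of 1 diet, with a smallest range within a diet of 2.85; these heifers share a diet, so this describes the pattern and tests no cause. Their median range of 4.06 lay at percentile 100 of random lists of the same mean level. Genes of that level thus did not all vary this widely. The test was chosen after this spread was seen, and it cannot tell whether RNA quality moved these genes more than others. The 3' minus 5' difference of 5 control genes was -0.62 to -0.33 in the 7 heifers with a score above 0. It was -0.38 to -0.16 in the other 11, while that of GAPDH, EEF1A1 and PPIB alone overlapped. Degraded RNA raises this difference, so the 7 heifers did not show more degraded RNA by this measure. Other differences in RNA quality or processing are left open as a source. Lymphocytes (upper quartile of marker ranges 2.37) and Kupffer cells (2.0025) varied less than the lower quartile of the interferon list (2.48), for lymphocytes by a narrow margin. An interferon response in some heifers may be the source, as a hypothesis, and no infection or pregnancy record was used here to test it.

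Of 5 BOLA-DQB1 probe sets, 2 were above 8 in 10 and in 6 heifers, both in Ctrl 21 and neither in 3, while another was at 12.2 to 14.2 in 17 heifers. The amount of antigen-presenting cells is argued against by BOLA-DRA, which ranged over 0.98 where the narrowest BOLA-DQB1 probe set ranged over 6.09. Allele differences under the probes may explain it: in 3 other MHC genes the probe sets disagreed at a median percentile of 99.8 among 1907 genes with several probe sets. The heifers' genotypes were not used here, so this remains a hypothesis.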

How the results depend on the processing

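The interferon score as a covariate was the only alternative among these tests chosen after the result was seen. No probe set passed the adjusted threshold in any of the 3 comparisons of diets under any alternative run with limma, where unadjusted p under 0.05 gave 801, 764 and 712. None of the genes named passed it either (2865 pairs of result and alternative, smallest adjusted p 0.315). GPX2 in ISe against Ctrl ran from -0.16 without Ctrl 21 to 0.013 without Ctrl 16, a reversal by the removal of a control at 3.75.

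The number of probe sets at an unadjusted p under 0.01 in OSe against ISe was 228 with array quality weights, against 99, and the cause was not tested. Leaving out heifers gave 84 (without ISe 22) to 339 (without ISe 7) in ISe against Ctrl, 89 (without Ctrl 1) to 173 (without Ctrl 16) in OSe against Ctrl and 65 (without OSe 23) to 172 (without ISe 7) in OSe against ISe.

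Gene lists called fell to 0 in each of the 3 comparisons with an estimated correlation between genes, and to 0 in each with fry. The runs of camera differ in the degrees of freedom of the test, which an estimated correlation limits to the 15 residual ones. They also differ in the correlation between genes, which was preset at 0.01. This correlation was estimated at 0.41 for the proteasome, 0.37 for heat shock chaperones, 0.45 for the cell cycle and 0.12 for lymphocyte markers. For these lists the preset was too low, so their p at the preset overstates the evidence. Gluconeogenesis and glycolysis went the other way, with an estimate of 0.0095, so a higher correlation does not account for its loss. The fewer degrees of freedom apply to this list too, but their share in the loss was not tested. Why fry called 0 was not tested either, and fry also differs in testing each list against no change, where camera tests it against the other genes. The interferon list itself was left out of the run with its score as a covariate, so its calls ended there by construction. In that run the count was 6 in ISe against Ctrl, 10 in OSe against Ctrl and 9 in OSe against ISe. The cause of the other changes was not tested. Without the covariate, leaving out heifers gave 7 (without ISe 22) to 12 (without ISe 7) lists in ISe against Ctrl. It gave 4 (without OSe 25) to 14 (without OSe 23) in OSe against Ctrl, and 6 (without ISe 18) to 15 (without ISe 29) in OSe against ISe. With quantile normalization 4 lists were higher and 2 lower in OSe against Ctrl, in place of 7 and 2. Quantile normalization ended the calls of cholesterol biosynthesis and complement in ISe against Ctrl, of complement, interferon-stimulated genes and oxidative phosphorylation in OSe against Ctrl, and of acute phase proteins, the unfolded protein response and endothelial markers in OSe against ISe. Median centring ended cholesterol biosynthesis in ISe against Ctrl and oxidative phosphorylation in OSe against ISe. Leaving out the dimmest probe sets ended interferon-stimulated genes and oxidative phosphorylation in OSe against Ctrl, and the unfolded protein response and oxidative phosphorylation in OSe against ISe. Fitting only the groups compared ended cholesterol biosynthesis, complement and the unfolded protein response in ISe against Ctrl, and oxidative phosphorylation and endothelial markers in OSe against ISe. The mean of all probe sets of a gene ended oxidative phosphorylation in OSe against ISe. The interferon covariate ended cholesterol biosynthesis, fatty acid oxidation, the unfolded protein response and ribosomal proteins in ISe against Ctrl, fatty acid oxidation in OSe against Ctrl, and oxidative phosphorylation, stellate cell and endothelial markers in OSe against ISe. The causes were not tested. Of the 32 calls, 22 ended without at least 1 heifer. Calls were also gained: 50 of the 2640 pairs of list result and alternative passed the threshold where the main run did not. The unfolded protein response in OSe against ISe ran from 3.51e-04 (without ISe 22) to 0.641 (without ISe 7, direction lower).

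The correlation of the ISe and OSe fold changes was 0.034 with separate controls, by construction, since shared controls add to it. It ran from 0.411 (without OSe 25) to 0.637 (without Ctrl 17). Signal over background limits the 30.6% of probe sets at or below the bacterial controls.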

Other observations

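The genes and relations in this part were chosen after the result was seen, and the tests of relations likewise. Some genes were near background in part of the heifers and high in the others. PRSS2, a trypsinogen of the pancreas, was at 9.41 to 9.95 in ISe 7, OSe 8, OSe 12 and Ctrl 21 and at 1.90 to 2.21 in the other 14. SERPINI2, a serine protease inhibitor, was at 12.6 in ISe 11 and at 2.61 to 4.58 in the other 17. CYP2B6, a cytochrome P450 that oxidises drugs, was at 3.06 in OSe 23 and at 9.08 or more in the other 17. The fructose transporter SLC2A5 was at 2.78 in Ctrl 16 and at 6.44 to 10.7 in the others. Haptoglobin (HP), an acute phase protein, ran from 6.11 in ISe 18 to 16.2 in OSe 25. FOS was up to 11.7 in Ctrl 1 and Ctrl 17 and at 5.63 to 9.54 in the other 16.

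Spread between heifers of a diet differed by group of genes. Scores of 21 of the 34 lists spread more than the 95th percentile of random lists, and 7 more than all 10000. Random lists were matched on mean level only, so any list whose genes vary together tends to exceed them. The within-diet SD was 1.34 for interferon-stimulated genes, 0.71 for MHC class II genes, 0.49 for immediate early genes and 0.36 for acute phase proteins. For the cell cycle (highest score in OSe 8) and Kupffer cell markers (highest in OSe 25) the SD was 0.39. The SD of a list is that of its score. This SD was 0.09 for selenoproteins (percentile 76.5) and 0.03 for hepatocyte markers (percentile 12.8).

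The 3' minus 5' difference went with the interferon split, and lay mostly lower in heifers with a score above 0, away from the direction of degraded RNA. It ran from -0.62 (ISe 22) to -0.33 (Ctrl 21) in the 7 heifers with a score above 0. In the other 11 it ran from -0.38 (OSe 19) to -0.16 (OSe 23), and only OSe 14 and OSe 19 overlapped the 7. The difference of GAPDH, EEF1A1 and PPIB alone did not separate them (-0.81 to -0.68 and -0.86 to -0.59). These contrasts between the sets were not tested. Within the 7 heifers with an interferon score above 0, the score and the 3' minus 5' difference had r = -0.704 (exact permutation p = 0.0802, adjusted p = 0.641 over 8 relations, rho -0.607, r without the 2 farthest heifers -0.633). Within the other 11, r was 0.229 (permutation p = 0.504, adjusted p = 0.675, rho 0.209, and 0.163 without the 2 farthest). For the 3' minus 5' difference of GAPDH, EEF1A1 and PPIB alone, r was 0.0574 in the 7 (rho 0.0357, 0.1704 without the 2 farthest; exact permutation p = 0.910, adjusted p = 0.910) and 0.385 in the 11 (rho 0.364, 0.578; permutation p = 0.247, adjusted p = 0.675).

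With lymphocyte markers r was -0.489 in the 7 (rho -0.321, -0.287 without the 2 farthest; exact permutation p = 0.268, adjusted p = 0.675) and 0.217 in the 11 (rho 0.209, 0.477; permutation p = 0.507, adjusted p = 0.675). With Kupffer cell markers r was -0.121 in the 7 (rho -0.357, -0.742 without the 2 farthest; exact permutation p = 0.790, adjusted p = 0.903) and 0.307 in the 11 (rho 0.355, 0.199; permutation p = 0.364, adjusted p = 0.675).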
